A study of Mus musculus with 15 samples.

How the data were processed

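RNA of mouse lung was measured on 15 single-colour Affymetrix expression arrays. Each group held 3 arrays. Per the labels' protocols, total RNA was extracted with TRIzol, cleaned on RNeasy columns and turned into biotinylated cRNA with the Affymetrix 3' IVT Express protocol. This protocol starts at the poly(A) tail, so probe sets read mostly the 3' end of a transcript. The values deposited by the authors are probe set intensities on a linear scale, 1 value per array for each of 45101 probe sets, from 0.48 to 17030. The scanner, background correction, summarization and scaling were not given in the sources used here. Between 1.46% and 2.01% of the values on each array equal exactly 1; where these come from is not given in the sources used here. Array medians lay between 90.9 and 99.5, so the deposited intensities had been brought to a common level, but the distributions were not identical between arrays. No array file with raw probe signals was used here.

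Probe sets were named through the platform annotation. It listed 35890 of the probe sets: 34958 with 1 gene symbol, 932 with several and 0 without; the other 9211 are unnamed here. Symbols were looked up by gene number in the RefSeq gene table of assembly GRCm38.p6, where 34741 probe sets matched and 0 symbols changed. Probe sets with several symbols and Affymetrix controls were left out of the tests. Each gene was represented by the 1 probe set with the highest mean log2 value over all 15 arrays, a choice that does not look at the groups. This left 18193 genes, of which 9010 had more than 1 probe set to choose from.

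Intensities were transformed as log2(intensity + 16) and compared with limma (version 3.58.1, in R 4.3.3; lmFit and eBayes, two-sided). P-values were adjusted with the Benjamini-Hochberg method over all 18193 genes, and a gene was called at an adjusted p under 0.05. Every adjusted p of a single gene below is from these fits. Fold changes are on the log2(intensity + 16) scale and understate changes of dim genes: 17.1% to 21.1% of the probe sets on each array lay below 16. The 12-month groups were fitted on their own 6 arrays, since the series describes them as a separate study, and the 7-month groups in 1 model of 9 arrays; 3 of these belong to a further group that is not reported here and enter the estimate of the spread and the choice of probe sets. The difference between the tumour effect at 12 months and the effect of the mutant genotype at 7 months was a contrast over all 15 arrays.

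Gene lists, 35 in all, were fixed together with the tests and alternatives before the data were examined. They were tested with limma's camera at its preset inter-gene correlation of 0.01, adjusted over the lists within a comparison. With the correlation estimated from the data, which is uncertain at these array numbers, no list kept its call in either comparison with wild type. That p is given beside each list. Counts of members are given over all genes tested and, where stated, adjusted over the list alone.

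The rule for named genes took a set fixed beforehand, with Smad4, Erbb2, Elf3 and Errfi1, in every comparison. It added up to 4 called members, by smallest adjusted p, of each list that passed camera or had at least 3 called members. It also took the 5 largest rises and 5 largest falls among called genes whose 3 values in 1 group all lay above those of the other. The text names a part of that set. Genes named for the difference between ages were taken by size among the called genes, after their values were seen.

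Labels of the 12-month arrays carry animal numbers except for 1 tumour, and those of the 7-month arrays give only replicate numbers. The labels do not say whether a 7-month array holds 1 animal, nor whether the 3 tumours come from 3 animals, so the p-values at both ages measure the spread between these samples, which can be technical in part. No pair of arrays held identical values, and arrays of 1 reported group correlated at 0.982 to 0.994 over genes.

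The steps were tested on simulated arrays drawn from the measured means and residual spread, with 200 of 18193 genes changed. For the tumour comparison, 35.8% of the genes changed 1.5-fold were recovered, 64.2% of those changed 2-fold and 89.4% of those changed 4-fold, with 6 false calls. For the mutant lungs at 7 months these shares were 49.3%, 83.6% and 98.5%. For the difference between ages they were 31.3%, 68.7% and 93.9%. In the camera test on simulated 12-month arrays, the 1 list that had been moved passed and 0 of the others did. The simulated genes were drawn independently of each other, so this does not test list calls where genes are correlated.

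The alternatives tried were quantile normalization, median centring, leaving out the dimmer genes, a variance trend with robust fitting, array weights and pseudocounts of 1 and 64. Others were the mean of all probe sets of a gene, leaving out probe sets whose names end in _x_at, and a common fit of all 15 arrays. Further ones were fits of only the groups compared, sex as a block, the replicate number as a block, and leaving out each array in turn. Lists were also tested with fry. A comparison of the tumours with the male wild type array alone was added after seeing the data.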

Results

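Lungs of wild type mice and of mice whose genotype includes a deletion of Smad4 were profiled at 2 ages. Smad4 is the shared partner of the SMAD proteins in TGF-beta and BMP signalling. The older set held 3 wild type lungs and 3 lung tumours of the mutant mice at 12 months. The younger set held 3 wild type and 3 mutant lungs at 7 months, taken per the series design before tumours had begun. The effects below are those of the whole genotype and are not assigned to Smad4 alone. All mice were of mixed background. Median intensity ranged from 95.7 to 99.5 over the 12-month arrays and from 90.9 to 94.3 over the 7-month arrays. Over genes, log2 intensities correlated at 0.982 to 0.994 within these groups. The ages were compared only through their own wild type lungs. With 3 arrays per group, the number of arrays limits the precision of every estimate below.

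The arrays differed in sex. At 12 months, Xist, the RNA of the inactive X chromosome, was at 6786 and 6917 on 2 wild type arrays and at 69.8 on the third, while all 3 tumours showed the Y-linked genes. At 7 months, 5 of the 6 arrays showed both Xist and the Y-linked genes at intermediate levels, and 1 wild type array showed the Y-linked genes without Xist. Control probe sets for 18S ribosomal RNA read 1700 ± 504 (SD, n = 3) in the tumours against 6381 ± 778 (n = 3) in wild type lung at 12 months. At 7 months they read 6953 ± 83.5 in wild type and 7199 ± 792 in mutant lung.

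**Figure D1:**
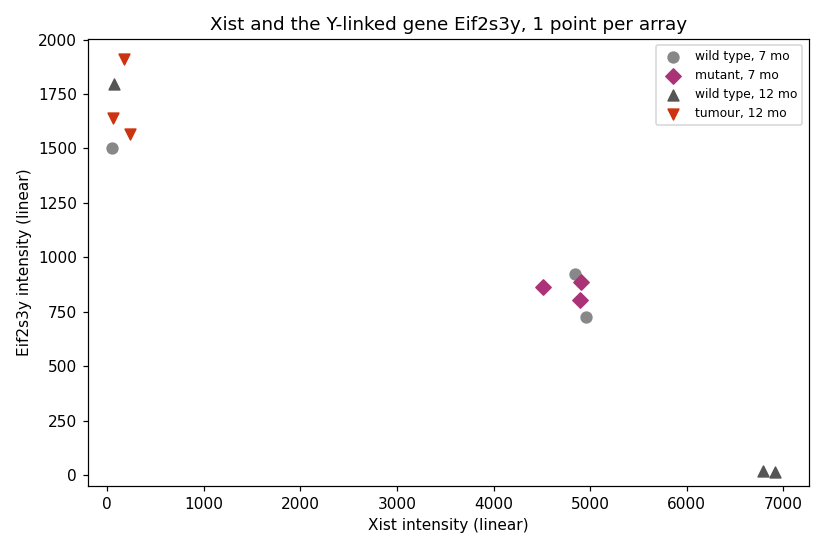
Xist intensity (x axis) against intensity of the Y-linked gene Eif2s3y (y axis), linear scales, 1 point per array, coloured by group. The 12-month arrays lie at 1 end or the other, while 5 of the 6 arrays at 7 months lie between.

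Smad4 comes first, since its level would check the labels. It read 3303 ± 364 in tumours and 2819 ± 137 in wild type lung at 12 months (n = 3 each, adjusted p = 0.213). At 7 months Smad4 read 3292 ± 109 in mutant and 3220 ± 73.7 in wild type lung (adjusted p = 0.799). None of its 3 probe sets was lower in the tumours or in the mutant lungs than in wild type, and 1 of them was 1.30-fold higher in tumours (adjusted p = 0.0343). Where the probe sets lie relative to the deleted part is not given in the sources used here. A sample of whole lung or of tumour can also hold cells without the deletion, and their share was not measured. These values therefore do not check the genotype.

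The series title names ErbB2, a receptor tyrosine kinase of the EGF receptor family, and the tumour comparison asked which genes separate tumours from wild type lung. Erbb2 was 1.77-fold higher in tumours (log2 fold change 0.82 ± 0.11 SE, adjusted p = 0.0103), at 308 ± 28.3 against 167 ± 18.9 (n = 3 each). Elf3, an epithelial transcription factor, was 3.77-fold higher (1.91 ± 0.20, adjusted p = 0.00573), at 1993 ± 494 against 506 ± 41.99. Errfi1, a feedback inhibitor of ErbB receptors, read 2483 ± 959 against 3157 ± 250 (adjusted p = 0.380). Its second probe set was 2.74-fold lower in tumours (adjusted p = 0.0129), so both lay lower and only the second was called. Erbb2 is in the series title, and Elf3 and Errfi1 were listed from prior knowledge of the published study, so these 3 are not independent evidence. Of 14 ErbB receptors and ligands measured, Erbb2 alone rose and 0 fell, over all genes and adjusted over the list alone.

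**Figure D2:**
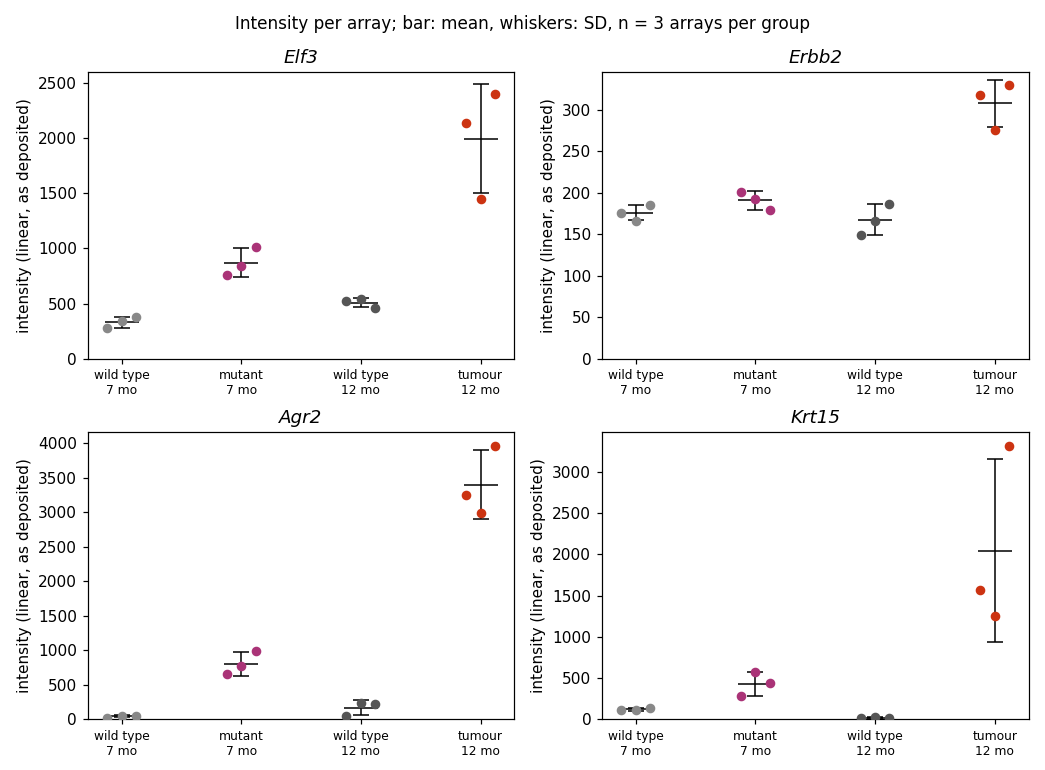
Intensity (y axis, linear, from 0) of Elf3, Erbb2, Agr2 and Krt15 on each array, by group (x axis). Points are arrays, bars are means and whiskers SD (n = 3); Elf3 and Agr2 lie higher in each mutant group than in its wild type, and Erbb2 only in the tumours.

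Most ciliated cell markers and part of the squamous, mucous and club cell genes were higher in tumours than in wild type lung. On the log2(intensity + 16) scale the largest rises were Krt15 (55.7-fold), a basal cell keratin, Sult1c1 (54.5-fold), a sulfotransferase, Alox12e (46.8-fold), a lipoxygenase, Wfdc18 (33.3-fold) and Glycam1 (24.5-fold). Mean wild type intensities of Krt15 (18.6), Sult1c1 (6.63), Alox12e (9.12) and Glycam1 (4.84) lay near or below the added 16, so the size and order of these folds depend on it. Of 24 squamous and basal cell genes, 11 rose and 0 fell (14 rose adjusted over the list alone), among them Krt14 (23.4-fold) and Krt17 (10.7-fold), keratins of stratified epithelium, and Serpinb5 (6.80-fold); wild type means of Krt14 (6.44) and Krt17 (9.79) also lay below 16 and that of Serpinb5 (21.6) near it. Ciliated cell markers rose in 25 of 26 cases, with a median log2 fold change of 1.40. Enkur (2.72-fold), Rsph9 (2.53-fold) and Hydin (2.38-fold), components of motile cilia, were among them. Of 27 mucous cell genes, 15 rose and 1 fell. They included Agr2 (21.7-fold), a disulfide isomerase of mucus-producing cells, the mucin Muc16 (9.29-fold) and Spdef (3.61-fold), a goblet cell transcription factor. These 3 lists passed camera (adjusted p = 7.24e-07, 3.61e-14 and 5.18e-05 in that order), and each had adjusted p = 0.417 with an estimated correlation.

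Epithelial junction genes rose in 18 of 22 cases and fell in 0 (adjusted p = 1.06e-11; adjusted p = 0.353 with an estimated correlation). Cldn2, a pore-forming claudin, was 7.02-fold higher (2.81 ± 0.11), the simple-epithelial keratin Krt18 was 2.66-fold higher and the splicing factor Esrp1 was 2.45-fold higher. Of 16 oxidative stress and glutathione genes, 11 rose and 0 fell, including Gpx2 (4.44-fold), Aldh3a1 (3.74-fold) and Gsta4 (2.69-fold). Of 15 club cell markers, 4 rose, among them Chad (4.20-fold) and Cldn10 (2.55-fold). Of 17 interferon response genes, 7 rose and 1 fell; Oas2 was 4.68-fold, Ifit1 2.94-fold and Irf7 2.70-fold higher. Of 18 glycolysis and hypoxia genes, 5 rose, including Egln3 (2.98-fold), an oxygen-sensing hydroxylase, and the glucose transporter Slc2a1 (1.62-fold). With an estimated correlation, adjusted p = 0.417 for the oxidative stress, 0.560 for the club cell, and 0.472 for the interferon and glycolysis lists.

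Part of the endothelial, alveolar type 1 and macrophage markers was lower in tumours. Endothelial markers fell in 17 of 26 cases and rose in 0, with a median log2 fold change of -1.02 (adjusted p = 1.46e-11; adjusted p = 0.417 with an estimated correlation). Erg was 2.80-fold, the receptor Tie1 2.36-fold and Pecam1 1.97-fold lower. Of 19 alveolar type 1 markers, 5 fell over all genes and 12 adjusted over the list alone, with 1 member rising on the latter count. Spock2 was 3.32-fold and Sema3e 1.66-fold lower (list adjusted p = 2.13e-05; adjusted p = 0.518 with an estimated correlation). Among the 21 alveolar type 2 markers 0 were called. Their median log2 fold change was -0.44, which passed camera (adjusted p = 0.00305; adjusted p = 0.733 with an estimated correlation). Of 22 macrophage markers, 9 fell and 0 rose, among them Itgax (4.27-fold lower), Cd68 (3.60-fold) and Ctsk (3.36-fold). Of 23 inflammatory cytokines and chemokines, 10 fell and 2 rose. The neutrophil and monocyte attractants Ccl3 (8.99-fold) and Cxcl2 (5.38-fold) and the cytokine Il1a (6.44-fold) were lower, and Lif was 2.31-fold higher. Both lists had adjusted p = 0.417 with an estimated correlation. The largest falls were Cxcl3 (11.2-fold), the lectin-like receptor Olr1 (log2 fold change -3.33), the zinc transporter Slc39a2 (9.22-fold), Ccl3 and the fibrinogen chain Fga (8.77-fold).

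Of 12 cardiac muscle markers, 11 rose in the tumour samples (median log2 fold change 1.23, adjusted p = 1.19e-08; adjusted p = 0.417 with an estimated correlation). Sln was 3.35-fold, Tnni3 2.81-fold and the atrial light chain Myl7 2.19-fold higher; mouse pulmonary veins also carry such muscle. Among 29 cell cycle genes 0 rose and 1 fell. In the TGF-beta and BMP pathway, 1 of 27 components rose, Bmpr1b (2.42-fold), and 6 fell, including Bmp6 (2.63-fold lower) and Tgfb1 (1.98-fold lower). Of 18 SMAD target genes, 3 rose and 2 fell: Id4 was 2.64-fold higher and Id2 1.52-fold lower. Of 20 WNT pathway genes, 5 rose and 1 fell. Dkk2 was 6.91-fold, Wnt11 2.71-fold and Wnt4 2.66-fold higher. The SMAD target and WNT lists did not pass camera (adjusted p = 0.940 and 0.739), nor did the TGF-beta and BMP list (adjusted p = 0.200). Of 15 NOTCH pathway genes 3 fell, including the endothelial receptor Notch4 (2.22-fold; list adjusted p = 0.0403; adjusted p = 0.417 with an estimated correlation). Among 22 fibroblast and matrix genes 2 rose and 4 fell, with Lum 5.14-fold higher and Mfap4 3.42-fold lower. Of 7 mesothelial markers 3 rose and 1 fell, and 3 rose and 3 fell adjusted over the list alone (camera adjusted p = 0.811); Msln was 7.47-fold higher and Lrrn4 2.28-fold lower. Smooth muscle markers passed upward with 1 of 11 called (adjusted p = 0.00688; adjusted p = 0.615 with an estimated correlation), and T and NK cell markers downward with 2 of 19 called (adjusted p = 0.0236; adjusted p = 0.518 with an estimated correlation). The lists of neutrophil (0 of 11 called), B and plasma cell (1 of 12), red blood cell (0 of 4) and adipose markers (1 of 5) did not pass. Nor did matrix proteases and inhibitors (3 of 17 higher), mesenchymal transition genes (3 higher and 3 lower of 11), lipid and sterol synthesis genes (1 of 15 lower), FOXO and insulin feedback genes (2 higher and 1 lower of 17), ErbB feedback genes (2 of 17 higher) or immediate early genes (1 higher and 3 lower of 16).

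In all, 1679 genes were higher and 1095 lower in tumours, of 18193 tested, with 736 and 281 of them changed at least 2-fold. The 3 values of 1 group all lay above those of the other for 37.5% of genes, against 10% by chance. With sex as a block, 1 gene was called (5595 genes had an unadjusted p under 0.05 without the block), because the block leaves 1 male wild type array to compare with. Against that array alone, with the spread pooled over all arrays, an alternative added after seeing the data, 1342 genes were higher and 827 lower, but 10 of the genes named above were no longer called. Fga (log2 fold change -1.65, from -3.13) and Lrrn4 (-0.69, from -1.19) shrank most. The others changed less: Cxcl3 was at -3.93 (from -3.48), Itgax -1.85 (from -2.09), Ctsk -1.60 (from -1.75), Lif 1.04 (from 1.21), Slc2a1 0.56 (from 0.69), Sln 1.49 (from 1.74), Tnni3 1.16 (from 1.49) and Myl7 0.93 (from 1.13). With 1 wild type array in place of 3, the loss of these calls alone does not point to sex. The counts without single arrays ranged from 622 to 1900 higher and from 220 to 1426 lower, and were lowest without wild type array 3.

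The question at 7 months was what the mutant genotype had changed before tumours. Elf3 was 2.55-fold higher in mutant than in wild type lung (1.35 ± 0.13, adjusted p = 0.000509), at 872 ± 130 against 332 ± 50.3 (n = 3 each). Erbb2 read 191 ± 11.3 against 176 ± 9.16 (adjusted p = 0.452), and Errfi1 5676 ± 1071 against 5817 ± 424 (adjusted p = 0.887). On the log2(intensity + 16) scale the largest rises were the glycoprotein Gp2 (log2 fold change 5.32), the antibacterial lectin Reg3g (39.1-fold), Wfdc18 (35.4-fold), the mucosal scavenger protein Dmbt1 (20.7-fold) and Cdhr1 (18.5-fold). Wild type means of Wfdc18 (15.2), Dmbt1 (12.9) and Cdhr1 (19.6) again lay near or below the added 16. Falls were small, the largest being Gria1 (1.90-fold), Mtr (1.71-fold), Upk3b (1.69-fold), AI506816 (1.61-fold) and Adamts8 (1.60-fold).

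Ciliated cell markers rose in 23 of 26 cases (median log2 fold change 1.01, adjusted p = 6.19e-27; adjusted p = 0.193 with an estimated correlation). Mlf1 was 2.79-fold, Rsph1 2.48-fold and Ccdc39 2.05-fold higher. Of 27 mucous cell genes 12 rose and 0 fell (16 rose adjusted over the list alone), with Agr2 15.4-fold and Muc20 2.14-fold higher. Members of the epithelial junction list rose in 12 of 22 cases, including Cldn2 (5.30-fold), the tight junction protein Tjp3 (2.20-fold) and the transcription factor Ehf (2.08-fold). Of 24 squamous and basal cell genes 5 rose: among them Dsc2 was 3.27-fold, Krt15 3.22-fold and the basal cell factor Sox2 2.15-fold higher. Of 16 oxidative stress genes 10 rose, with Gpx2 2.78-fold and Aldh3a1 2.56-fold higher. Of 15 lipid and sterol synthesis genes 8 rose (Cyp51 and Sqle 1.63-fold, Me1 1.57-fold). Club cell markers rose in 8 of 15 cases (Chad 2.83-fold, Cldn10 1.63-fold), alveolar type 2 markers in 6 of 21 (Hc 1.45-fold, S100g 1.34-fold) and interferon response genes in 4 of 17 (Ifit1 2.17-fold, Usp18 1.95-fold). With an estimated correlation, adjusted p = 0.206 for the mucous and lipid lists and 0.193 for the junction and oxidative stress lists. It was 0.278 for the squamous and alveolar type 2, 0.290 for the club cell and 0.463 for the interferon list.

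Endothelial markers fell in 5 of 26 cases over all genes and in 18 adjusted over the list alone, Erg 1.42-fold, Gpihbp1 1.39-fold and Pecam1 1.25-fold (adjusted p = 3.13e-11; adjusted p = 0.278 with an estimated correlation). Of 19 alveolar type 1 markers 2 fell, the anchoring protein Akap5 1.49-fold and Spock2 1.42-fold, and of 11 smooth muscle markers 1 fell, Smtn (1.25-fold). Both lists had adjusted p = 0.310 with an estimated correlation. Mesenchymal transition genes passed downward with 0 of 11 called (adjusted p = 0.00598; adjusted p = 0.193 with an estimated correlation), as did the NOTCH list with 0 of 15 called (adjusted p = 0.0195; adjusted p = 0.310 with an estimated correlation). Of 20 WNT pathway genes 4 rose, among them Wnt5a (1.73-fold) and Wnt4 (1.58-fold), and the list did not pass (median log2 fold change 0.01, adjusted p = 0.378). Of 14 ErbB receptors and ligands 0 were called, and of 18 SMAD target genes 0 were called. In all, 1168 genes were higher and 253 lower (255 and 0 at least 2-fold), with full separation for 26.1% of genes against 10% by chance. The falling count was the less stable: it was 116 to 180 without single arrays, lowest without mutant array 3, 37 in a fit of only these 2 groups (730 higher) and 596 without the dimmer genes.

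**Figure D3:**
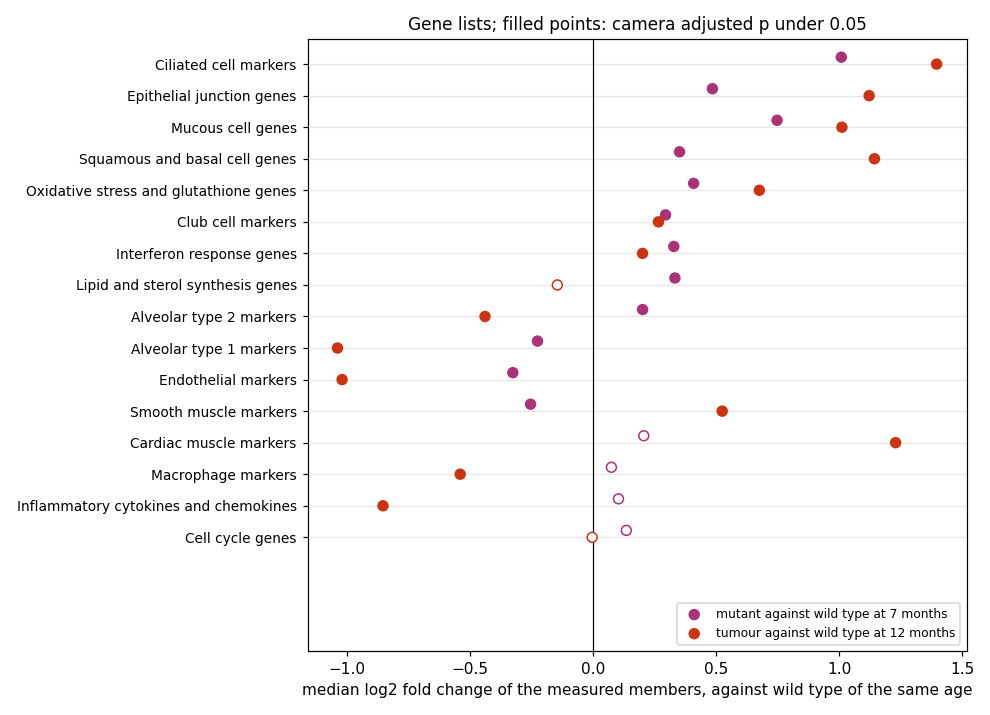
Median log2 fold change of the measured members (x axis) for 16 of the gene lists (y axis), each comparison against wild type of its age. Filled points passed camera at the preset correlation and open points did not; ciliated cell markers lie above 0 and endothelial markers below 0 in each comparison.

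The effect in tumours at 12 months was then set against that of the mutant genotype at 7 months, each relative to wild type of its age. Age, tumour against whole lung, and any batch between the sets differ together here. Erbb2 differed (0.71 ± 0.13 on the log2 scale, adjusted p = 0.0148), while for Elf3 the difference did not pass (0.56 ± 0.24, adjusted p = 0.229), nor for Agr2 (0.49 ± 0.57, adjusted p = 0.711). In all, 319 genes had a higher and 257 a lower effect in tumours. The largest of the former were Prp2 (4.15), Krt15 (4.11), Glycam1 (3.95), the lipoxygenase Alox15 (3.88) and the developmental factor Six2 (3.79). The largest of the latter were Slc26a4 (-3.51), Olr1 (-3.13), Slc39a2 (-2.92), Stra6l (-2.92) and Ccl3 (-2.91). Wild type intensities enter these values and differ between the ages: Krt15 read 18.6 at 12 and 116 at 7 months, Alox15 23.9 and 188, and Ccl3 863 and 36.1. Those of Glycam1 (4.84 at 12 months), Six2 (6.51) and Krt15 lay near or below the added 16 at 12 months, and that of Prp2 (2.73) at 7 months, so size and order depend on it. With 1 added in its place Glycam1 (adjusted p = 0.0884), Slc26a4, Olr1 and Slc39a2 were not called, and the last 3 were also not called without several single arrays. Without single arrays the counts ranged from 162 higher and 108 lower, without mutant array 1, to 857 higher and 973 lower, without tumour array 2.

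Calls overlapped between the ages. Of the 1168 genes higher in mutant lung at 7 months, 758 were also called higher in tumours, where independent lists would share 108, and 2 of the 1679 genes higher in tumours were lower at 7 months. Of the 253 lower genes 95 were shared, where 15.2 would be by independence, and 3 of the 1095 genes lower in tumours were higher at 7 months. These comparisons have separate wild type arrays. Counting signs alone, 1077 of the 1168 genes (92.2%) had a positive log2 fold change in tumours, with a median of 0.83 against 0.62 at 7 months. Of the 253 genes, 217 (85.8%) had a negative one.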

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

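The tests of the Xist and Y-linked genes and the test of which arrays the male wild type array lies nearer to were chosen after the values had been seen, and the latter replaced a first version whose choice of genes was biased; the difference between ages, sex as a block and the splits were planned.

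The effect of the genotype differed between the ages for 319 genes with a higher and 257 with a lower effect in tumours, by a test of the difference itself. Among all genes named in the report, the effect was higher in tumours for Erbb2 (0.7114 on the log2 scale), Krt14 (3.126), Krt15 (4.11), Krt17 (2.034), Krt18 (1.18), Serpinb5 (1.79), Sult1c1 (3.134), Alox12e (3.612), Alox15 (3.876), Glycam1 (3.946), Prp2 (4.154), Six2 (3.791), Muc16 (2.767), Spdef (1.388), Esrp1 (0.6601), Gsta4 (0.7036), Oas2 (1.807), Id4 (1.268), Msln (2.308), Mtr (1.132), AI506816 (1.072) and Smtn (0.7044). It was lower for Slc26a4 (-3.513), Olr1 (-3.129), Slc39a2 (-2.923), Stra6l (-2.923), Ccl3 (-2.912), Il1a (-2.459), Cxcl2 (-2.21), Mfap4 (-1.727), Cyp51 (-1.023), Tie1 (-0.8979) and Sqle (-0.6377). Of 100 joint splits of the 12-month and 7-month arrays, 8, the real one among them, gave 576 genes or more. The real split gave 576 and the highest of the 8 gave 990. All 8 keep the real grouping at 12 months and so still hold the tumour effect, a structure of the samples; they are not splits without a change, and the 8 decide nothing about chance. Among the 90 splits that regroup the 12-month arrays the highest gave 6 genes. These mix tumour and wild type arrays within a group, which widens the spread, so their low counts decide nothing about chance either.

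The other splits of the samples were too few for a share under 0.05: each comparison of 3 arrays against 3 has 10 splits. For tumours against wild type the real split gave 2774 genes and the highest of the others 0. For mutant against wild type lung at 7 months these were 1421 and 0. In each case 1 split, the real one, gave as many genes. All splits but the real one mix tumour or mutant with wild type arrays within a group, which widens the spread. Their count of 0 is therefore not that of arrays without a change.

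Sex and genotype were unevenly combined at 12 months, where 2 of the 3 wild type arrays showed a female and the third a male signature, and all 3 tumours a male one. If sex were the source of the calls, the male wild type array would lie with the tumours. Of 1264 genes called against the 2 female wild type arrays alone, it lay nearer to the tumours for 78, or 6.17%, which argues against sex as the cause of most calls. With sex as a block the median change of the 2774 genes went from 0.80 to 0.75 on the log2 scale and the median SE from 0.14 to 0.20. The blocked change is the tumours minus the male wild type array, which had taken part in calling these genes, so its sign and size decide nothing about sex. For single genes sex stays open, and Fga is 1 whose change was much smaller against the male array (-1.65 against -3.13).

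At 7 months 5 of 6 arrays carried both Xist and Y-linked genes. All 5 had Eif2s3y, Kdm5d and Uty between 0.1 and 0.9 of the level on the male-only array and Xist at over 10 times its level there, which restates the observation and tests no cause: RNA of males and females pooled in 1 sample stays open, since the labels do not give the animals per array. Probe set background is argued against by the 12-month arrays, where the genes of the other sex reached at most 0.0345 of their level in that sex. Carry-over of RNA between samples would look like pooling and cannot be told apart from it, because both add transcripts of the other sex; 1 array of the 6 was without Xist. The mean level of the Y-linked genes was 0.549 and 0.576 of the male-only array in the other wild type arrays and 0.566, 0.582 and 0.565 in the mutant arrays; no biological explanation was tested.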

How the results depend on the processing

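Of 2205 values of named genes under the alternatives, 1974 kept their result, 228 were weaker, 2 stronger and 1 reversed; the comparison with the male wild type array was chosen after seeing the data. The reversed value, not called in any case, was Errfi1 in mutant against wild type lung at 7 months, 0.0796 without mutant array 1 (-0.189 without mutant array 3). Each named gene entered once per alternative, and 816 of the values came from leaving out single arrays. A gene not called in either fit counted as kept, so the total is not a share of stable genes. With sex as a block, most values of genes named in the tumour comparison were weaker, meaning that a call was lost.

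For tumours against wild type, sex as a block left 1 gene higher and 0 lower, and all 15 arrays in 1 model gave 2735 and 2191. Without single arrays there were 622 (without wild type array 3) to 1900 (without tumour array 2) higher and 220 to 1426 lower. With an estimated correlation 0 lists passed in this comparison and 0 in mutant against wild type lung at 7 months.

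For mutant against wild type lung at 7 months, the genes lower were 596 without the dimmer genes, 555 with variance trend and robust fit, 127 with array weights, 459 with pseudocount 64, 157 with the replicate block and 104 with all 15 arrays. Only these 2 groups gave 730 higher and 37 lower, and leaving out single arrays gave 116 (mutant array 3) to 180 lower (wild type array 2). Replicate numbers did not pair the samples: 4 of the 9 arrays in the 7-month model correlated best with an array of their own number.

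For the difference between ages, genes lower were 425 with array weights, 164 with pseudocount 1 and 387 with pseudocount 64. Single arrays left out gave 162 (mutant array 1) to 857 higher (tumour array 2) and 108 to 973 lower. Sex as a block was not run at 7 months, where 5 of the 6 reported arrays held RNA of both sexes and wild type array 3 only the male signature.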

Other observations

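The ratio of the 3' to the 5' control probe sets of Gapdh, a measure of RNA integrity, was 1.37 ± 0.17 (SD, n = 3) in tumours and 1.37 ± 0.02 in wild type lung at 12 months. At 7 months it was 1.96 ± 0.43 in wild type and 1.74 ± 0.21 in mutant lung. Immediate early and heat shock genes, which respond to tissue handling, had 0 of 16 members called at 7 months, with a median log2 fold change of 0.02 (camera adjusted p = 0.807).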
